A study of Mus musculus with 4 samples.

How the data were processed

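Gene expression was measured on microarrays in whole cochleae, the auditory part of the inner ear, dissected from mouse embryos at embryonic day 15. The labels assign 2 arrays to wild-type embryos and 2 to embryos labelled N-myc ko, and call the arrays of a group biological replicates. Per the labels' protocols, embryos were genotyped by PCR, total RNA was extracted with a column kit, and cDNA was amplified with the WT Expression Kit, fragmented and biotinylated. Whether a sample was 1 embryo or a pool is not given in the sources used here.

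The deposited values are on a log2 scale, the scale that RMA gives, and run from 3.63 to 14.3. Per the series' design text and the submitters' processing notes, the authors used RMA, with the affy package, to correct the background, normalise within and between arrays, and summarise the probes of a gene into 1 expression value. Versions, the array design and the assignment of probes to genes are not given in the sources used here. Scanner files were not used here, so the background correction and the probe-level normalisation were taken as they stand. Each of the 23879 rows carries 1 Ensembl mouse gene ID, and no ID is repeated. The table pairs no ID with a gene name. The Ensembl column of the reference gene table at hand, which lists 49997 mouse genes, matched 0 of these IDs. Genes are therefore given by Ensembl ID, at most 2 in each direction. The transcript of the targeted gene, Mycn, and the lists of genes by symbol that had been fixed before the data were examined (MYC partners, ribosome biogenesis, cochlear cell types, neighbouring tissues, sex-linked genes and others) were not analysed here.

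The main test was limma 3.58.1 in R 4.3.3 (lmFit and eBayes without a brightness trend, two-sided) on all rows and all 4 arrays, with N-myc ko minus wild-type as the contrast and Benjamini-Hochberg adjustment. A gene was called changed at an adjusted p of at most 0.14, the false discovery rate limit that the design text names, and counts under 0.05 are given beside it. The design text names significance analysis of microarrays (SAM) as the authors' test. With 2 arrays against 2 it has only 6 label arrangements, so it was rebuilt here as an alternative. The rule fixed for named genes took the 12 called genes with the widest change in each direction whose groups do not overlap, and was kept to the first 2 of each because the table gives IDs alone. No array-level depth exists for such data, and the number of arrays limits the precision: the fit had 2 residual degrees of freedom and borrowed 4.33 from the other genes.

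In place of the symbol lists, cell cycle phase lists keyed by Ensembl ID were added after the data were seen. They come from published marker pairs trained on mouse embryonic stem cells sorted by phase, distributed with the R package scran. A gene belongs to a phase if it is more often the higher than the lower partner of a pair in that phase alone. The lists were tested with limma's camera (preset correlation 0.01, two-sided, called at an adjusted p of at most 0.05 over the 3 lists), with camera at an estimated correlation, with fry and with the rank form of camera. The S and G2M genes were set against the G1 genes in a linear model of the difference of their means on each array. Each list's median was also placed among 10000 random lists matched on mean expression in 40 bins, which treats genes as independent.

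Alternatives fixed before the data were examined were the stricter limit, SAM, a brightness trend with and without robust variances, array weights, a further quantile normalisation, centring on the median, a test of the genes above the median brightness alone, the replicate number as a block, and leaving out each array in turn. Cyclic loess normalisation and a limit of 2-fold were added later. On data simulated with the spread of these arrays, with 200 of 23879 genes changed, limma at the 0.14 limit recovered 91.0% of changes of 1 on the log2 scale and 100.0% of changes of 2, with 15.3% and 11.9% of calls false. It recovered 0% of changes of 0.5. SAM recovered 88.5%, 100.0% and 0% of the same changes of 1, 2 and 0.5. The simulation changed far fewer genes than the 8280 called on the real data, and it held no shift with brightness. Benjamini-Hochberg adjustment is stricter where fewer genes change. The simulated rates therefore do not show how well changes of 0.5 or less were detected in the real data.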

Results

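The data set compared gene expression in the whole cochlea of wild-type and N-myc ko mouse embryos at embryonic day 15, with 2 arrays in each group. N-myc is a transcription factor of the MYC family. Values were obtained for 23879 genes, each identified by an Ensembl gene ID and measured as the authors' RMA expression value on the log2 scale. Arrays of the same group were the most alike. Pearson's r across genes was 0.995 between the wild-type arrays and 0.995 between the N-myc ko arrays, and lay between 0.983 and 0.987 for the 4 pairs of arrays from different groups. These correlations are across genes, which are not independent replicates. The first principal component held 73.4% of the variance and separated the groups, with both wild-type arrays on one side and both N-myc ko arrays on the other. The robust SD of a single array, estimated from the difference between the replicates of a group, was 0.116 in wild-type and 0.118 in N-myc ko cochleae. The labels do not say whether each sample was a separate embryo, so the p-values measure the spread between these samples.

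The main comparison asked which genes are expressed at a different level when N-myc is mutated. Of the 23879 genes, 8280 were called changed at an adjusted p of at most 0.14 in limma, and 3561 of these rose and 4719 fell in N-myc ko cochleae. Most changes were small. The log2 change was under 0.5 for 5868 of the called genes (70.9%), and from 0.5 to 1 for a further 2183. At least a 2-fold change was seen for 229 called genes, of which 141 rose and 88 fell, and at least a 4-fold change for 23, of which 15 rose and 8 fell. At an adjusted p under 0.05, 3572 genes were called, 1614 higher and 1958 lower, and 220 of them changed at least 2-fold. Leaving out 1 array lowered the count of calls to 5150 without wild-type replicate 1, 4931 without wild-type replicate 2, 3151 without N-myc ko replicate 1 and 6559 without N-myc ko replicate 2. The count of genes that rose at least 2-fold went from 141 to 227 without N-myc ko replicate 2.

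Among the called genes, the widest rises were those of ENSMUSG00000046411 and ENSMUSG00000059762. ENSMUSG00000046411 had a log2 value of 6.56 ± 0.07 (SD, n = 2) in wild-type and 10.21 ± 0.45 (SD, n = 2) in N-myc ko cochleae, a 12.5-fold rise (log2 change 3.65, SE 0.20, limma adjusted p = 0.0024). ENSMUSG00000059762 went from 7.93 ± 0.26 to 11.47 ± 0.68 (SD, n = 2 each), an 11.6-fold rise (log2 change 3.54, SE 0.30, limma adjusted p = 0.0063). The widest falls were those of ENSMUSG00000067006 and ENSMUSG00000027070. ENSMUSG00000067006 went from 8.08 ± 0.05 to 5.13 ± 0.16 (SD, n = 2 each), 7.72-fold lower in N-myc ko (log2 change -2.95, SE 0.11, limma adjusted p = 0.00095). ENSMUSG00000027070 went from 9.50 ± 0.04 to 6.62 ± 0.20 (SD, n = 2 each), 7.34-fold lower (log2 change -2.88, SE 0.12, limma adjusted p = 0.00095). For each of these 4 genes both N-myc ko arrays lay on the same side of both wild-type arrays, as the rule for named genes required. The same held for all 8280 called genes. A low p with 2 arrays per group all but requires such separation, so it is no separate support for the calls. Over all genes 64.9% had such separated groups, against 33.3% expected by chance for 2 arrays against 2. A shift with brightness, described below, moved both N-myc ko arrays the same way and can by itself raise this share.

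**Figure D1:**
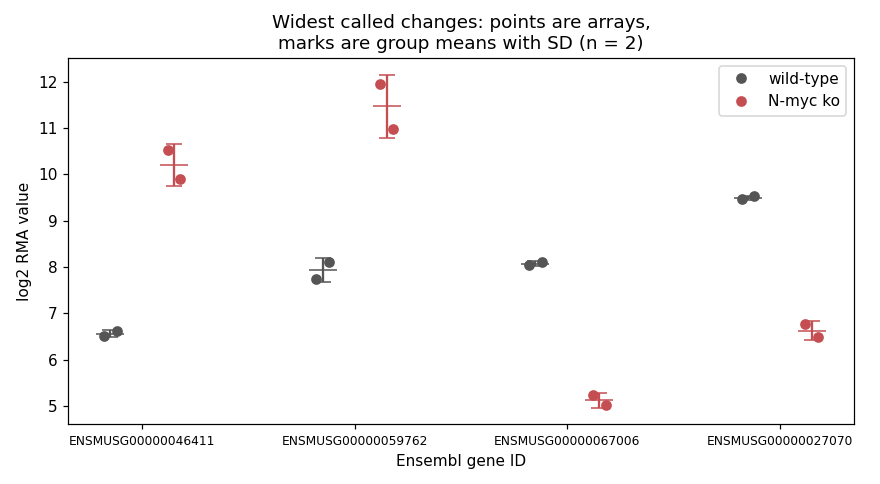
Log2 RMA values (vertical axis) of the 4 genes with the widest called changes (horizontal axis, Ensembl gene IDs). Points are single arrays, in grey for wild-type and red for N-myc ko, and bars are the group mean with its SD (n = 2); ENSMUSG00000046411 and ENSMUSG00000059762 were 12.5-fold and 11.6-fold higher in N-myc ko, and ENSMUSG00000067006 and ENSMUSG00000027070 were 7.72-fold and 7.34-fold lower.

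The direction of change went with the brightness of a gene, taken as its mean log2 value over the 4 arrays. Of the called genes above the median brightness of the table, 653 rose and 3877 fell, and of those below it, 2908 rose and 842 fell. The median log2 change was 0.16 for the 3725 genes with a mean between 6 and 7 and -0.21 for the 3934 genes with a mean between 8 and 9. Between replicates the corresponding medians were 0.026 and 0.033 for wild-type replicate 2 minus replicate 1, and -0.076 and 0.057 for N-myc ko replicate 2 minus replicate 1. At the ends of the range the median change between the groups was smaller. It was 0.026 for genes with a mean under 5, where the wild-type replicates differed by 0.051, and -0.053 for genes over 11. The N-myc ko arrays accordingly had a narrower distribution of values. The lower quartiles were 5.76 and 5.79 on the wild-type arrays and 6.01 and 5.93 on the N-myc ko arrays, and the upper quartiles were 9.14 and 9.18 against 8.94 and 9.004. The 2-fold changes were spread over dim and bright genes, with 65 rises and 55 falls among the brighter genes and 76 rises and 33 falls among the dimmer genes.

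**Figure D2:**
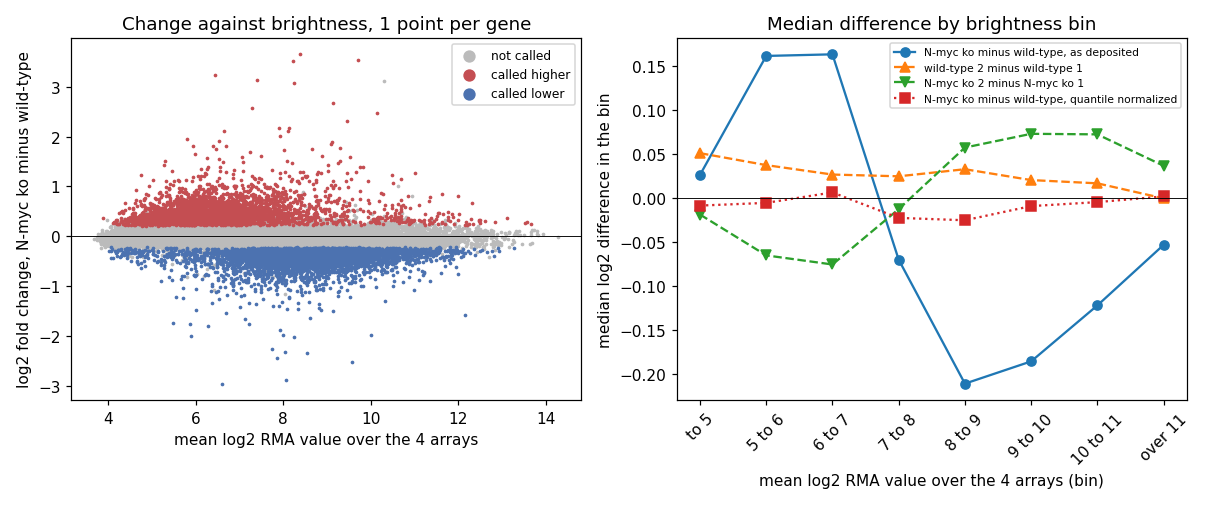
Left, log2 fold change of each gene (N-myc ko minus wild-type) against its mean log2 RMA value over the 4 arrays, with genes called at an adjusted p of at most 0.14 in red (higher) and blue (lower). Right, the median log2 difference in bins of the same mean, for the groups as deposited, between the replicates of each group, and for the groups after quantile normalisation; the deposited values shift from 0.16 between 6 and 7 to -0.21 between 8 and 9, and after quantile normalisation these medians are 0.0062 and -0.025.

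When the deposited values were quantile normalised again, which gives the 4 arrays the same distribution, 4816 genes were called, 2402 higher and 2414 lower. Of the 8280 genes called on the deposited values, 3920 (47.3%) were called in the same direction and 0 in the opposite direction. Of the 229 genes with at least a 2-fold change, 226 (98.7%) were called in the same direction. Cyclic loess normalisation gave 4962 calls, 2646 higher and 2316 lower, and called 226 of the same 229 genes in the same direction. Centring each array on its median gave 8253 calls, 4687 higher and 3566 lower. The share of higher calls was thus 43.0% as deposited, and the split between higher and lower depended on the scaling.

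Markers of the cell cycle phases had median log2 changes below 0 on the deposited values, and most members of each list were not called. Of 121 measured genes of the S phase list, 1 rose, 42 fell and 78 were not called, and the median log2 change was -0.21. Of 101 measured genes of the G2M list, 1 rose, 39 fell and 61 were not called, with a median of -0.21. Of 113 measured genes of the G1 list, 3 rose, 20 fell and 90 were not called, with a median of -0.12. Adjusted over the list alone, 42 S genes, 39 G2M genes and 8 G1 genes fell, and 1, 1 and 2 rose. After quantile normalisation the calls were fewer, with 4 S genes higher and 13 lower, 2 G2M genes higher and 11 lower, and 5 G1 genes higher and 3 lower. Camera with a preset correlation placed all 3 lists below the other genes (adjusted p = 3.2e-06 for S, 3.2e-06 for G2M and 0.0056 for G1). With an estimated correlation the adjusted p was 0.46 for S, 0.46 for G2M and 0.51 for G1, so no list was called. Without N-myc ko replicate 1 the medians were -0.13 for S, -0.14 for G2M and -0.051 for G1, and the preset-correlation call of G1 was lost while those of S and G2M were kept. Without N-myc ko replicate 2 the G1 median was -0.19.

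These list members are bright genes, with a median mean log2 value of 9.17 for S, 9.16 for G2M and 9.64 for G1, a range in which most called genes fell. Random lists matched on brightness had a median log2 change of -0.15 for S (central 95% -0.20 to -0.10), -0.16 for G2M (-0.21 to -0.10) and -0.14 for G1 (-0.19 to -0.093). The S list's median stood at the 1.31 percentile of its matched lists, the G2M list's at the 2.41 percentile and the G1 list's at the 76.9 percentile. The share of members that fell was 34.7% for S and 38.6% for G2M, within the central 95% of matched lists (22.3% to 38.8% and 22.8% to 40.6%). For G1 it was 17.7%, below that range (21.2% to 38.1%). After quantile normalisation the medians were -0.066 for S, -0.068 for G2M and 0.011 for G1, and camera with a preset correlation called none of the 3 lists (adjusted p = 0.12 for S, 0.12 for G2M and 0.51 for G1).

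**Figure D3:**
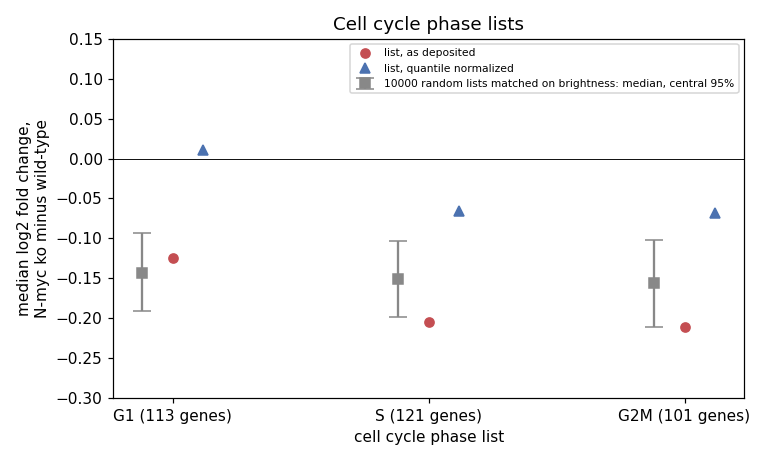
Median log2 fold change (N-myc ko minus wild-type, vertical axis) of the G1, S and G2M lists (horizontal axis) as deposited (circles) and after quantile normalisation (triangles), beside the median and central 95% of 10000 random lists matched on brightness (squares with bars). The S and G2M lists, at -0.21 each, lie just below their matched ranges, and the G1 list, at -0.12, lies inside its range.

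The S and G2M genes were also compared with the G1 genes within each array, which removes only the part of a shift that the lists share. The G1 genes were brighter, and the medians of random lists matched on brightness still differed by -0.0092. The mean log2 value of the S and G2M genes minus that of the G1 genes was -0.22 ± 0.027 (SD, n = 2) in wild-type and -0.29 ± 0.020 (SD, n = 2) in N-myc ko cochleae, a difference of -0.078. Both N-myc ko arrays (-0.28 and -0.31) lay below both wild-type arrays (-0.20 and -0.23). In a linear model with 2 residual degrees of freedom this difference had an SE of 0.024 and a 95% interval from -0.18 to 0.023, which includes 0. After quantile normalisation it was -0.073, with an interval from -0.17 to 0.029. With 2 arrays against 2, the smallest p that an exact two-sided permutation test can give is 0.333. Counted by gene, 81 of 222 S and G2M genes (36.5%) and 20 of 113 G1 genes (17.7%) fell (two-sided Fisher's exact test, p = 0.00039). After quantile normalisation 24 of 222 (10.8%) and 3 of 113 (2.65%) fell (the same exact test, p = 0.0098). This test takes the genes as independent, which they are not.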

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

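The 8280 calls became 3572 at an adjusted p under 0.05, 4816 after quantile normalisation, 4962 after cyclic loess (chosen after seeing the data), 4757 among the genes above the median brightness and 13393 with SAM at a false discovery rate of 14%, and ranged from 3151 to 6559 when 1 array was left out. The 3561 higher calls became 1614 at the stricter limit and 692 among the brighter genes, and ranged from 1436 to 3044 without 1 array. The 4719 lower calls became 1958 at the stricter limit, 8596 with SAM, 2414 after quantile normalisation and 2316 after cyclic loess, and ranged from 1715 to 3515 without 1 array. SAM estimates its false discovery rate from 6 label arrangements, most of which mix the groups and so put the group difference into the spread. Its rate of 14% may therefore be too low. The test of the brighter genes covers fewer genes, and gave 121 calls with at least a 2-fold change, 65 higher and 56 lower. The 2-fold rises ranged from 111 to 227 without 1 array, and under the other settings that tested all genes the 2-fold counts stayed within 1.5 times the values reported. A fit with 1 array left out assumes that the lone array varies like the other group. The cause of the changes in count was not tested, apart from the fewer genes or arrays in some settings. The replicate numbers share no stated origin (the deviations of same-numbered arrays correlate at 0.12), and the fit with the replicate block gave 8835 calls and lost none of the 4 named genes. These genes kept their direction and their calls under every setting that included them. ENSMUSG00000067006 is not among the brighter genes. The phase lists were chosen after seeing the data. The G1 median turned to 0.011 after quantile normalisation and 0.027 after cyclic loess, and among the brighter genes, at -0.13, camera placed it above the other genes. It ranged from -0.19 to -0.051 without 1 array, and its call was lost without N-myc ko replicate 1; the S and G2M medians ranged from -0.27 to -0.13 and from -0.26 to -0.14, with their calls kept. The S and G2M calls were lost after quantile normalisation (-0.066 and -0.068), after cyclic loess (-0.051 and -0.053) and among the brighter genes (-0.20 and -0.22). With the medians at -0.21, -0.21 and -0.12, the calls of S, G2M and G1 were also lost with an estimated correlation (adjusted p = 0.46, 0.46 and 0.51) and with fry (adjusted p = 0.12, 0.12 and 0.24), and kept by the rank test. The planned averaging of probe sets and the planned test of all rows could not differ from the main test, since the table has 1 row per gene, and the planned fits of Mycn and of the symbol lists were not run for lack of gene names.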

Other observations

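Quantile normalisation and leaving out each array were planned before the data were examined. The limits used to weigh explanations with them, the other splits and the tests of the phase lists were chosen after the results were seen. The widest gap between replicates belonged to ENSMUSG00000086503, picked after its values were seen. Its log2 value was 5.54 in wild-type replicate 1 and 11.9 in wild-type replicate 2, a gap of 6.40, and 11.6 and 12.1 in the N-myc ko replicates. The next widest gap of any gene was 2.93. Its change between the groups (log2 3.11, SE 1.81) was not called (limma adjusted p = 0.27). Such a gap may reflect a difference in the make-up of wild-type replicate 1, such as the sex of its embryos. This was not tested, since sex-linked genes were not among the genes that could be named, and it leaves open what part of the group difference comes from that sample. Without wild-type replicate 1, 5150 genes were called. Of the 8280 calls on all arrays, 4570 were called in the same direction without it, and so were 225 of the 229 with a 2-fold change. Replicates differed by more than 2-fold for 48 genes in wild-type and 34 genes in N-myc ko cochleae. For 1 gene the table gives the same value, 7.63, on all 4 arrays.

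The 8280 calls were set against the other splits of the arrays. There are 3 splits of 4 arrays into 2 and 2, and 1 of them, the real one, gave as many calls. The highest count of the other splits was 0, with 193 and 87 genes at an unadjusted p under 0.05. Each other split puts 1 array of each group on either side, so the group difference enters its residual spread and works against calls. The count of 0 is therefore no support for the real split. Too few splits exist for a share under 0.05.

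Dim genes tended to rise and bright genes to fall in N-myc ko cochleae, though the dimmest genes (mean under 5) and the brightest (over 11) moved little. This shift alone is argued against as the whole cause of the calls: 47.3% of the called genes were called in the same direction once quantile normalisation had removed it. That share does not show what caused the remaining calls, since other differences between the samples would also survive this normalisation. The widest median shift of any bin was -0.21 on the log2 scale. Removing it could hardly undo a 2-fold change, so the 98.7% of 2-fold changes called again do not test the shift. The 2-fold changes were also picked by their size in the same values. The shift may still account for many of the small changes. A broad effect of the mutation on dim and bright genes (median log2 change -0.211 in the bin from 8 to 9) and a difference in RNA, labelling or hybridisation common to both N-myc ko arrays cannot be told apart, since each group has 2 arrays and no batch is given. The make-up of the whole-cochlea samples was not examined either, since the lists of cell types and neighbouring tissues were not analysed.

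A hypothesis from the phase lists is that S and G2M genes were slightly lower than G1 genes in N-myc ko cochleae beyond the shift with brightness. The S and G2M medians stood at the 1.31 and 2.41 percentiles of matched random lists, so the shift may not account for all of their fall. By the share of members that fell, however, S and G2M lay within the central 95% of matched lists (84.8 and 94.3 percentiles). By that measure it was G1 that stood out, with fewer falls than its matched lists (0.19 percentile). The difference between the S and G2M median and the G1 median was -0.086, at the 0.54 percentile of matched pairs of lists, and -0.078 after quantile normalisation. Over the arrays, the difference of list means had a 95% interval from -0.18 to 0.023, which includes 0. Matched lists treat genes as independent, while the estimated correlation within these lists was 0.22 for S and 0.23 for G2M, and camera after quantile normalisation called neither list (adjusted p = 0.12 for both). A fall of cycling-cell genes and the shift with brightness therefore cannot be told apart for these lists.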
